A study of Mus musculus with 4 samples.

How the data were processed

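Bone-marrow-derived macrophages of C57BL/6 mice were cultured for 7 days and profiled by ChIP-seq, per the labels. The labels list 4 samples: an input and an H3K27me3 library from M-CSF culture, and an input and an H3K27me3 library from culture labelled G-CSF. Groups were taken from the sample titles, with 1 library per group. The input libraries were not analysed here. Per the labels' protocols, histone-DNA complexes were isolated with an antibody from sonicated nuclei, libraries were amplified by PCR, and sequencing was done on an Illumina instrument. The sources disagree in 4 places. The titles name H3K27me3 and the antibody field H3K4me3, the titles and treatment field name G-CSF and the growth protocol GM-CSF, and the series design text speaks of 2 different histone modifications. The submitters' processing notes name the genome build mm9 and CASAVA 1.4, while the coordinates of the lists fit another build.

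The authors deposited 1 annotated peak list per H3K27me3 library. The peak caller, its control and its settings are not given in the sources used here; the column layout is that of MACS2 output. The pileup is the signal height at each peak, per the file headers, and its scaling is not given in the sources used here. Columns 6 and 8 lost their headers to a spreadsheet error and were read as −log10 of the p-value and q-value that the authors' caller gave, from the column order and because column 6 was the larger. The fold enrichment of each peak is a ratio over the control or local background, per the file headers, and every deposited value was at least 2. The deposited peak length is in bp and equals end minus start plus 1. Each list names at most 1 gene and element per peak. These scores are the authors' own and were used only to describe, rank or filter peaks within a list. Read counts are not in the lists used here, so the depth is unknown and no interval that needs it is given.

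The genome build was checked with the RefSeq gene table of GRCm38.p6. Of the peaks with a gene, 77.0% (M-CSF) and 76.6% (G-CSF) had a symbol found in the table. The annotated element overlapped the RefSeq gene of that symbol in 97.7% and 97.8% of these, with a lowest value of 95.4% and 95.6% on chromosome 17, and in 1.49% and 1.13% after a shift of 1 Mb. Coordinates are therefore given as the files give them and read as GRCm38. Peaks lay on 20 chromosomes, the autosomes and X.

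The design, the 17 gene lists, the rule for named genes and a set of other settings were fixed before the data were examined. The covered share of a locus as a measure between the libraries, the matching by locus length and the percentile limits were added after the files were opened, so the covered differences, among them that of the GM-CSF-associated genes, rest on a later choice. The design foresaw promoters around transcription start sites. The gene table used here has no strand, so a locus was instead the RefSeq span of a gene with 2 kb on both sides, for 21634 loci: the protein-coding genes and every list member. A locus was marked in a library if a peak overlapped it by at least 1 bp, and its covered share is the percent of its bases under peaks. Of 498 listed symbols 489 matched a current symbol, 8 an older one and 1 none on these chromosomes. For each list, the number of marked members was set against 10000 random lists of the same size, matched by locus length in 10 bins. The balance (loci marked in M-CSF only minus G-CSF only) and the mean covered difference were set against 10000 random lists drawn from genes marked in either library. Both percentiles used only the list's members marked in either library, with random lists of that size matched by locus length. The covered shares and differences in points given in the text average all members of a list. The percentile counts ties at their midpoint, and values outside 2.5 to 97.5 were called. These percentiles describe these libraries and are no p-values. Neighbouring genes can share a peak, and how reads shared by similar genes (the Oas, Ccl, Ear and H2 families) were treated is not given in the sources used here.

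Peaks were shared if they overlapped by at least 1 bp. The share that chance gives was the mean of 100 random placements of the other list on the same chromosomes with the same widths. Shares of peaks and loci have 95% Clopper-Pearson intervals, which cover counting error only and treat neighbouring peaks as independent. The named genes are, in each list, up to 6 members with the largest difference in covered bases and up to 3 most covered in both libraries; over all genes, 10 per direction with the most bases covered within 5 kb in 1 library and none in the other, leaving out predicted, small RNA, olfactory and vomeronasal receptor genes; and Il6, Tnf, Il10, Il12b, Il1b and Il23a. Members named beyond this rule, such as the MHC class II genes and the unmarked members, were chosen after their values were seen. Single values of some list members are not reported here.

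Settings fixed in advance were the stricter 50% of each list by q, lists of equal length, peaks within 3 kb joined, autosomes and X only, an overlap of 50% of the shorter peak, flanks of 1 kb and 5 kb, a minimum of 500 bp covered, and shares of bases. Added after seeing the data were no flank, 50% of the locus covered, peaks of at least 1 kb only, the authors' own gene per peak, and rotation of the other list. The code was tested on simulated data over 21631 genes: covered bases and the 50% overlap call were right for 150 of 150 intervals each, 10 of 10 planted lists of 20 genes passed percentile 97.5, and 5 of 100 unchanged lists fell outside 2.5 to 97.5. The simulated lists tested only the balance percentile, with marks drawn independently for each gene and library, unlike neighbouring genes that share a peak. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.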

Results

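H3K27me3, a histone mark laid down by Polycomb repressive complexes and found over silent genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in macrophages grown from the bone marrow of C57BL/6 mice. The labels name 4 libraries, each from cells kept for 7 days with a growth factor. One H3K27me3 library and 1 input library came from cells given M-CSF, the growth factor that drives macrophage formation. The other H3K27me3 and input libraries came from cells labelled as given G-CSF, a growth factor of neutrophils. The same labels' growth protocol names GM-CSF and M-CSF instead, so the group is called here the library labelled G-CSF, or the G-CSF library for short. The antibody field of both H3K27me3 libraries names H3K4me3, a mark of active promoters, while their titles name H3K27me3. Peak lists of the H3K27me3 libraries were analysed. There was 1 library per group, so no difference below has a replicate check, and no p-value between the groups is given. The sequencing depth of the libraries is not given in the sources used here.

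The M-CSF list held 69951 peaks over 316.9 Mb, and the G-CSF list held 59487 peaks over 322.2 Mb. The peaks were broad. Their median width was 1743 bp in the M-CSF list and 2231 bp in the G-CSF list. Peaks of at least 10 kb made up 11.4% of the M-CSF list (7961 peaks) and 14.5% of the G-CSF list (8622 peaks), and held 54.8% and 59.0% of the covered bases. The widest peak of both lists lay over the Hoxc cluster, a row of homeobox genes that set position along the body axis. It spanned 268 kb in the M-CSF list (chromosome 15, 102877893 to 103146304, fold enrichment 2.80) and 293 kb in the G-CSF list (102857880 to 103150865, fold enrichment 2.81), and held 9 coding genes from Hoxc13 to Hoxc4. Other peaks among the widest covered Cux2, a homeobox gene of neurons, and Pax2, a regulator of kidney development, in the M-CSF list. In the G-CSF list they covered Lhx1, Uncx and Lmx1b, homeobox genes of the embryo. A peak over the mast cell tryptase genes Tpsb2 and Tpsg1 and the calcium channel gene Cacna1h was among the 10 widest in both lists, at 185 kb and 266 kb.

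The labels disagree on the antibody, so gene groups typical of both marks were compared. All 95 developmental transcription factor genes of a list fixed in advance had a peak in both libraries, with 95% Clopper-Pearson limits of 96.2% to 100%, against a mean of 38.9 and 38.7 of 95 in random lists of matched gene length. On average 93.7% of each locus was covered by M-CSF peaks and 93.1% by G-CSF peaks. Pax2 was covered to 98.9% and 97.4%, and the muscle stem cell regulator Pax7 to 91.9% and 89.4%. The median width of the peaks at the developmental loci was 32.4 kb in the M-CSF library and 32.9 kb in the G-CSF library. A peak was counted here once for each locus it overlapped (139 and 127 overlaps), so a peak over several genes weighs more. Housekeeping genes were largely bare. Of 45 such loci, 2 had an M-CSF peak (4.44%, 95% interval 0.543% to 15.1%) and 4 had a G-CSF peak (8.89%, 2.48% to 21.2%), where random lists averaged 18.5 and 18.3. The glycolytic gene Gapdh, the actin gene Actb and the RNA polymerase II gene Polr2a had no peak in either list; unmarked genes named here and below were picked after their values were seen. The largest difference among housekeeping genes was at Tfrc, the transferrin receptor, whose locus was covered to 6.16% in the M-CSF and 55.7% in the G-CSF library, where it held 5 peaks, the longest of them a 192 kb peak that begins inside it. A locus here is the gene's span with 2 kb on both sides, and covering says nothing of how much of the mark the cells carried.

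Genes that define macrophages were largely bare as well. Of 27 macrophage identity genes, 22 had no peak in either library, and 3 were marked in each, against a random mean of 12.2 and 12. The unmarked genes included Spi1, which encodes the myeloid master regulator PU.1, the M-CSF receptor gene Csf1r, the integrin gene Itgam, the lysozyme gene Lyz2 and the endotoxin receptor genes Tlr4 and Cd14. The only member marked in both libraries was Fcgr3, an IgG receptor gene, covered to 11.2% and 15.5%. The high-affinity IgG receptor gene Fcgr1 was covered to 22.0% in the G-CSF library and had no M-CSF peak. The GM-CSF receptor gene Csf2ra was covered to 10.8% in the M-CSF library and had no G-CSF peak. Among 31 pattern receptor and NF-kB genes, 23 had no peak. Exceptions were Nfkb2, an NF-kB subunit gene (59.4% in M-CSF, 39.8% in G-CSF), the DNA sensor gene Aim2 (40.7% and 41.6%) and Tlr5, the flagellin receptor gene, with 24.1% in the G-CSF library and no M-CSF peak.

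T and NK cell genes and fibroblast and endothelial genes carried the mark more often than random lists in both libraries. Of 22 T and NK cell genes, 19 had an M-CSF peak and 20 a G-CSF peak, against random means of 9.97 and 9.79. The T cell regulator Gata3 was covered to 85.3% and 83.0%, and the surface antigen gene Thy1 to 100% in both. The mean covered share of this list was 47.7% in the M-CSF and 58.4% in the G-CSF library. Over the list's 20 members marked in either library, the difference lay at percentile 2.40 among random lists. By covered bases, its largest contrasts were Lef1, a Wnt effector of T cells (64.4% and 92.3%), and the CD3 zeta gene Cd247 (8.73% and 33.4%). Next came the CD8 beta chain gene Cd8b1 (3.90% and 70.9%), Bcl11b (26.1% and 38.9%), the kinase gene Zap70 (9.67% and 43.6%) and Cd5 (0% and 29.3%). The call of the list's mean difference was lost under every other setting that measures the covered shares anew. Its percentiles were 3.22 (flank of 1 kb), 4.70 (flank of 5 kb), 11 (stricter 50% of each list), 2.87 (lists of equal length), 3.66 (no flank) and 3.94 (peaks of at least 1 kb). Over only the loci with at least 500 bp covered or with 50% of the locus covered in either library, it lay at 3.17 and 30.7. By the authors' own gene a locus is only marked or not, so its percentile of 19.4 restates the balance. Among 12 B cell genes, 7 had an M-CSF peak and 8 a G-CSF peak, against random means of 5.51 and 5.45, inside the central 95% of random lists. The marked ones included the B cell identity gene Pax5 (85.3% and 90.1%) and the kinase gene Blk (100% in both). Of 14 erythroid and megakaryocyte genes 12 had an M-CSF peak and 9 a G-CSF peak, against random means of 5.41 and 5.37. The G-CSF count lay at percentile 97.2, inside the central 95% of random lists, but outside it in 6 of 9 other settings. The 9 marked in both included the band 3 gene Slc4a1 (100% in both), Tal1 (32.5% and 80.2%) and the platelet glycoprotein gene Gp9 (5.07% and 89.2%). Peaks in the M-CSF library only lay at the erythroid regulator Klf1 and the red cell membrane gene Rhag, with 25.8% and 7.75% of the locus covered. Of 20 fibroblast and endothelial genes 18 had an M-CSF peak and 15 a G-CSF peak, against random means of 10.2 and 9.88, and 15 were marked in both, with Col1a1, a collagen gene, covered to 100% in both and the VEGF receptor gene Kdr to 10.8% and 44.5%. Both counts of this list fell inside the central 95% with 50% of the locus covered (percentiles 91.8 and 89.5). The G-CSF count also did with a flank of 5 kb (96.3).

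**Figure D1:**
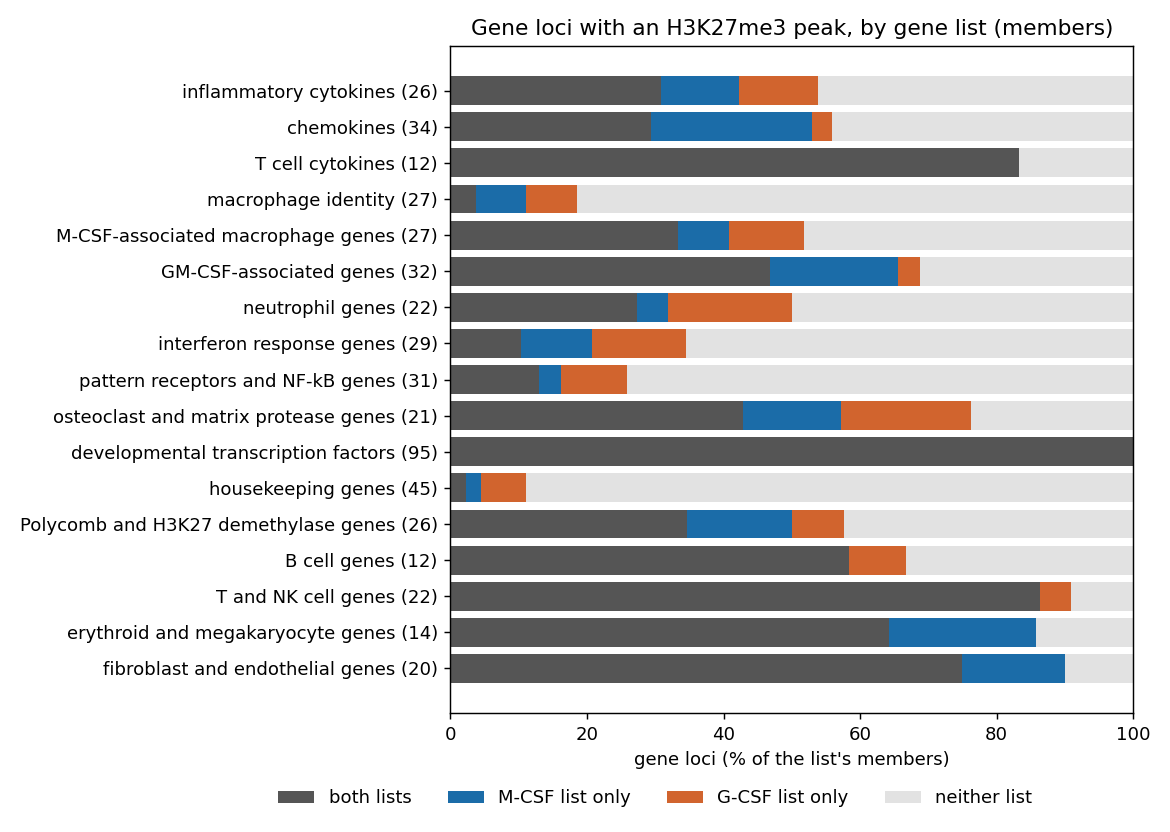
Stacked bars give, for each gene list, the percent of its loci with a peak in both libraries, in the M-CSF library only, in the G-CSF library only or in neither, and the number in brackets is the list's size. All 95 developmental transcription factors were marked in both libraries, and 40 of 45 housekeeping genes in neither.

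Wide peaks overlapped a peak of the other library more often than narrow ones. Of the M-CSF peaks, 29956 (42.8%, 95% Clopper-Pearson interval 42.5% to 43.2%) overlapped a G-CSF peak by at least 1 bp. Of the G-CSF peaks, 28656 (48.2%, 47.8% to 48.6%) overlapped an M-CSF peak. Placing the other list at random on the same chromosomes 100 times gave 20% and 22.6%. The lists had 196.6 Mb in common, 44.4% of the 442.5 Mb covered in either. Sharing followed width. Peaks under 1 kb overlapped the other list in 16.9% of cases for M-CSF and 20.1% for G-CSF, against 12.8% and 12.9% by random placement. Peaks of at least 10 kb did so in 94.6% and 92.7% of cases, against 46.0% and 49.7%. The median width was 4489 bp for shared and 1035 bp for unshared M-CSF peaks. Of the peaks of at least 10 kb with a q of at most 0.05, all 208 of the M-CSF list and 1093 of 1103 of the G-CSF list were shared. The 10 that were not included peaks over Stx11, a vesicle fusion gene of immune cells (chromosome 10, 12923855 to 12947798, intron, 23.9 kb), and over Notch4, a receptor gene of blood vessels (chromosome 17, 34562958 to 34577613, intron, 14.7 kb). Notch4 was named after its value was seen. These intervals cover counting error only.

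**Figure D2:**
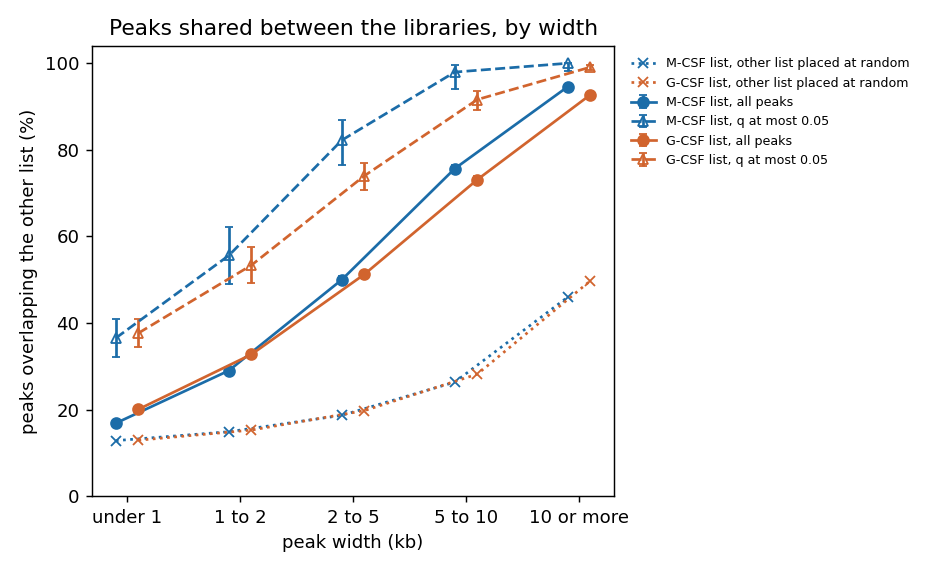
The share of peaks that overlap a peak of the other library (vertical axis, percent) is plotted by peak width (horizontal axis, kb), for all peaks (circles), peaks with q of at most 0.05 (triangles) and the other list placed at random (crosses), with 95% Clopper-Pearson bars on the measured shares. Sharing went from 16.9% and 20.1% in the narrowest class to 94.6% and 92.7% in the widest.

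Over 21634 gene loci, 8043 (37.2%) had a peak in both libraries, 1902 (8.79%) in the M-CSF library only, 1680 (7.77%) in the G-CSF library only and 10009 in neither. The order of the one-sided classes turned with lists of equal length (1569 in M-CSF only, 1884 in G-CSF only), with 50% of the locus covered (579 and 809) and with peaks of at least 1 kb (1371 and 1515). The series title ties the mark to cytokine transcription, so cytokine genes were compared. Of 26 inflammatory cytokine genes 8 were marked in both libraries, 3 in the M-CSF library only, 3 in the G-CSF library only and 12 in neither. Il6, a driver of fever and the acute phase, was marked in the M-CSF library only. Its longest peak there lay in an intron (chromosome 5, 30013667 to 30015726, 2.06 kb, fold enrichment 2.02), and 22.5% of its locus was covered. Il12a, the p35 subunit of interleukin-12, was marked in the G-CSF library only, by a peak of 10.7 kb annotated to its 5' UTR (chromosome 3, 68685362 to 68696095, fold enrichment 2.12) within a covered share of 78.9%. Tnf, Il1b, Il12b and Il23a, which encode the main inflammatory cytokines of macrophages, had no peak in either list, but M-CSF peaks covered 0.991 kb within 5 kb of Tnf and G-CSF peaks 2.34 kb within 5 kb of Il12b. Il10, an anti-inflammatory cytokine gene, had an M-CSF peak of 253 bp that covered 2.77% of its locus, and no G-CSF peak; within 5 kb of it the M-CSF list covered 2.10 kb and the G-CSF list 1.76 kb. The longest peaks at Il6 and Il12a were not in the stricter 50% of their lists, and by the authors' score neither passed a q of 0.05.

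Other inflammatory cytokine genes were covered in both libraries. The alarmin gene Il33 was covered to 85.9% in the M-CSF and 50.1% in the G-CSF library, the RANK ligand gene Tnfsf11 to 47.1% and 58.6%, the B cell survival factor gene Tnfsf13b to 69.8% and 74.8%, and Il11 to 70.9% and 82.2%. The balance of loci marked in 1 library only was 0, at percentile 47.3 of random lists of marked genes, and the mean covered share was 17.3% and 19.8% (percentile 30.6). Of 12 T cell cytokine genes, 10 had a peak in both libraries and none in 1 library only. With at least 500 bp covered, 8 were marked in the M-CSF and 10 in the G-CSF library. The mean covered difference was -3.77 points (percentile 41.1), and 11.9 points (percentile 95.6) with the stricter 50% of each list. Il9 and Il24 were covered to 100% in both, Il5 to 100% and 60.9%, Il17a to 43.4% and 89.9%, Il2 to 3.22% and 31.8%, Il17f to 0.742% and 20.7%, Il21 to 15.4% and 31.1%, and Il13 to 53.6% and 32.1%.

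Chemokine genes were marked more often in the M-CSF library. Of 34 loci 10 were marked in both libraries, 8 in the M-CSF library only, 1 in the G-CSF library only and 15 in neither. The balance of 7 lay at percentile 99.6 among 10000 random lists of marked genes with matched locus length. The mean covered share was 25.6% in the M-CSF and 18.4% in the G-CSF library. Taken over the 19 members marked in either library, the difference lay at percentile 98. The percentile was 91.4 with a flank of 5 kb and 94.7 with the stricter 50% of each list. Over only the loci covered by at least 50% in either library, the difference lay at percentile 72.2. Ccl22, a chemokine for regulatory T cells, was covered to 36.2% in the M-CSF library by 2 peaks. The peak with the most bases inside the locus was intronic (chromosome 8, 94744931 to 94748177, fold enrichment 2.06). Cxcl13, which attracts B cells, was covered to 42.5% by a peak at its 5' UTR (chromosome 5, 95954309 to 95958393, fold enrichment 2.25). Cxcl1, which attracts neutrophils, was covered to 44.8% by a peak at its 5' UTR (chromosome 5, 90888152 to 90891877, fold enrichment 2.05). By the authors' score, none of the 3 peaks with coordinates given here passed a q of 0.05. Their −log10 q was 0.533 (Ccl22), 0.598 (Cxcl13) and 0.552 (Cxcl1). None of these 3 genes had a G-CSF peak at its locus. Within 5 kb of Ccl22, however, G-CSF peaks covered 3.68 kb and M-CSF peaks 8.05 kb, while Cxcl13 and Cxcl1 had no G-CSF peak within 5 kb. The others marked in the M-CSF library only were Ccl19, Xcl1, Ccl28, Pf4 and Ccl20, named after their values were seen, and the 8 loci lay in 8 separate regions. Ccl1 was covered to 93.7% and 53.0%, and the eosinophil chemokine gene Ccl11 to 70.8% and 40.4%. The peak at Ccl1 reached beyond the locus and was longer in the G-CSF list (83275 bp, against 15605 bp). At Ccl11 the M-CSF peak was the longer (13036 bp, against 10233 bp). The chemokine gene marked in the G-CSF library only was Cxcl11 (56.4%), a pseudogene in the reference annotation. Cxcl12, Cxcl14 and Ccl24 were covered to at least 84.3% in both. Ccl2, Ccl3, Ccl4 and Ccl5, the abundant inflammatory chemokine genes of macrophages, had no peak in either. With the stricter 50% of each list the balance was 2 (percentile 85.0), and counting only loci covered by at least 50% it was 1 (percentile 77.4).

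Genes associated with GM-CSF culture, which favours antigen-presenting cells, also had more of their length covered in the M-CSF library. Of 32 loci 15 were marked in both libraries, 6 in the M-CSF library only, 1 in the G-CSF library only and 10 in neither. The mean covered share was 24.6% in the M-CSF and 17.4% in the G-CSF library, and the balance of 5 lay at percentile 95.6. Taken over the 22 members marked in either library, the covered difference lay at percentile 99.6. Ciita, the master switch of MHC class II expression, carried an M-CSF peak of 22.9 kb in its introns (chromosome 16, 10496606 to 10519479, fold enrichment 2.27) and was covered to 62.5%, against 1.28% in the G-CSF library. By the authors' score this 22.9 kb peak did not pass a q of 0.05 (−log10 q of 0.829). The MHC class II genes themselves, named after their values were seen, were covered to 64.3% and 0% (H2-Aa), 73.3% and 28.1% (H2-Ab1) and 43.4% and 28.3% (H2-Eb1). Without these 3 genes the covered difference of the list lay at percentile 94.1, and without Ciita as well at 80.1. The cytokine signalling inhibitor gene Socs2 was covered to 45.0% and 20.5%, and the dendritic cell regulator Zbtb46 to 44.6% and 36.2%. Other members went the opposite way. The growth factor receptor gene Flt3 was covered to 22.1% in the M-CSF and 74.8% in the G-CSF library, the lymph node homing receptor gene Ccr7 to 0% and 56.9%, the costimulator gene Cd86 to 1.33% and 24.4%, and the nitric oxide synthase gene Nos2 to 66.7% and 79.7%. The difference lay at percentile 97.1 with a flank of 5 kb and at 96.4 with the stricter 50% of each list. Over only the loci covered by at least 50% in either library, it lay at 85.2. By the authors' own gene, where it restates the balance, it lay at 92.9.

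**Figure D3:**
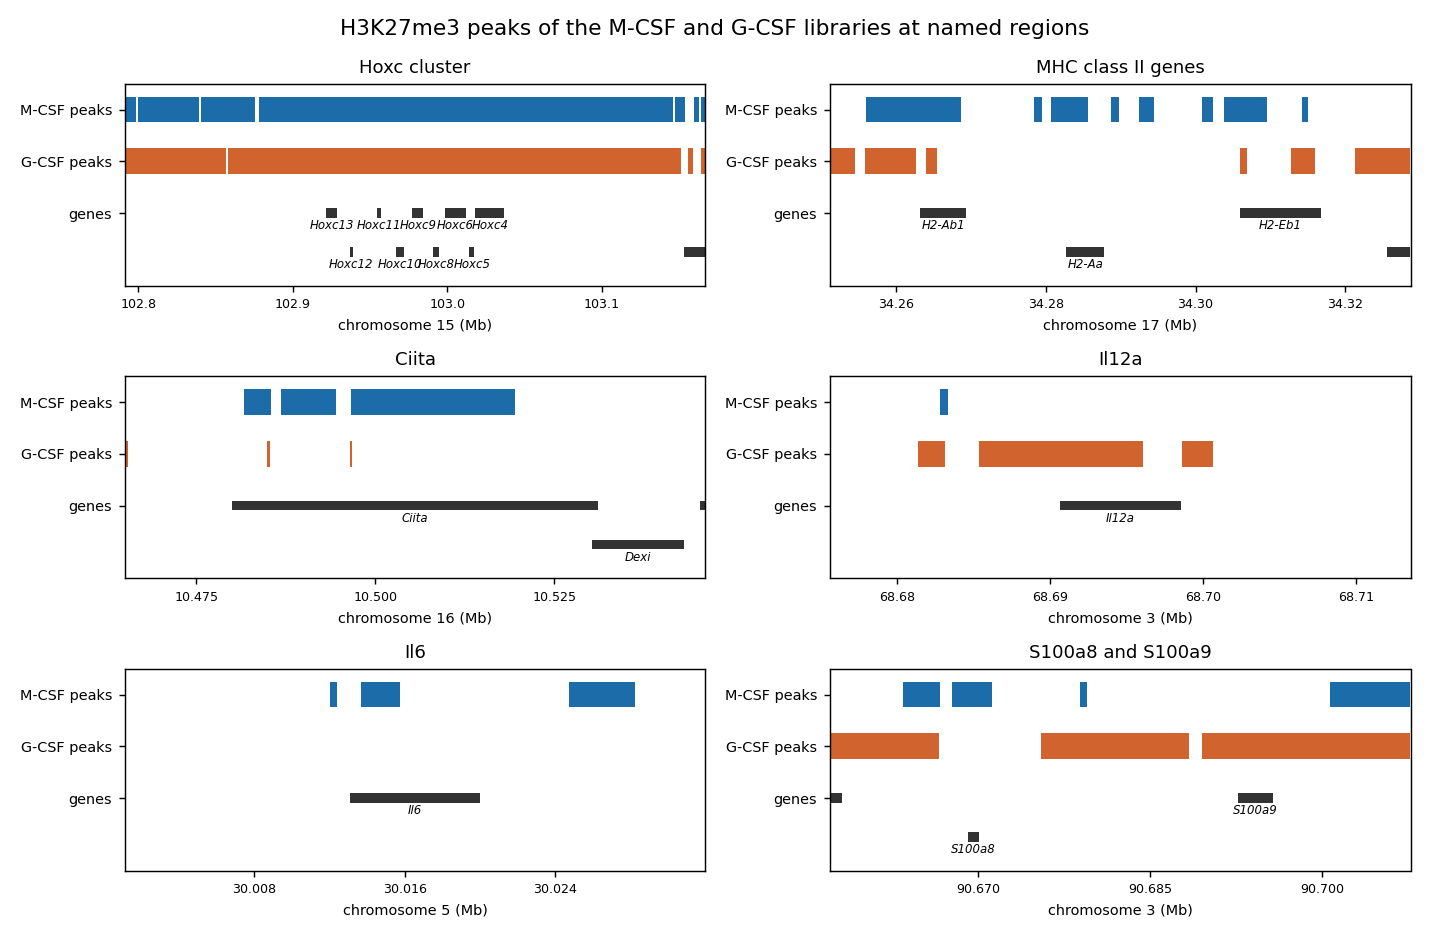
Bars mark the M-CSF peaks (upper row) and G-CSF peaks (middle row) above the coding genes (dark bars) at 6 regions, with the horizontal axis in Mb along the chromosome and peaks trimmed at the panel edges. One peak covers the Hoxc cluster in both libraries, while the 22.9 kb M-CSF peak in Ciita has a G-CSF peak of 301 bp at its edge, and the 10.7 kb peak at Il12a in the G-CSF list only.

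Genes associated with M-CSF macrophages showed no such tilt as a group. Of 27 loci 9 were marked in both libraries, 2 in the M-CSF library only, 3 in the G-CSF library only and 13 in neither, and the mean covered share was 5.71% and 8.99% (percentile 21.4). Single members differed. The scavenger receptor gene Marco was covered to 14.7% in the M-CSF and 76.2% in the G-CSF library, with an intronic G-CSF peak on chromosome 1 from 120480107 to 120499912 (fold enrichment 2.27). Gas6, a ligand for the uptake of dying cells, was covered to 1.02% and 45.3%, and the chitinase-like gene Chil3 to 0% and 26.6%. The lectin gene Cd209a was covered to 96.7% and 41.6%. Mertk, the receptor for Gas6, and F13a1, a clotting factor gene, were covered to under 3% in both libraries. The mannose receptor gene Mrc1, the arginase gene Arg1 and Cd163 had no peak in either.

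**Figure D4:**
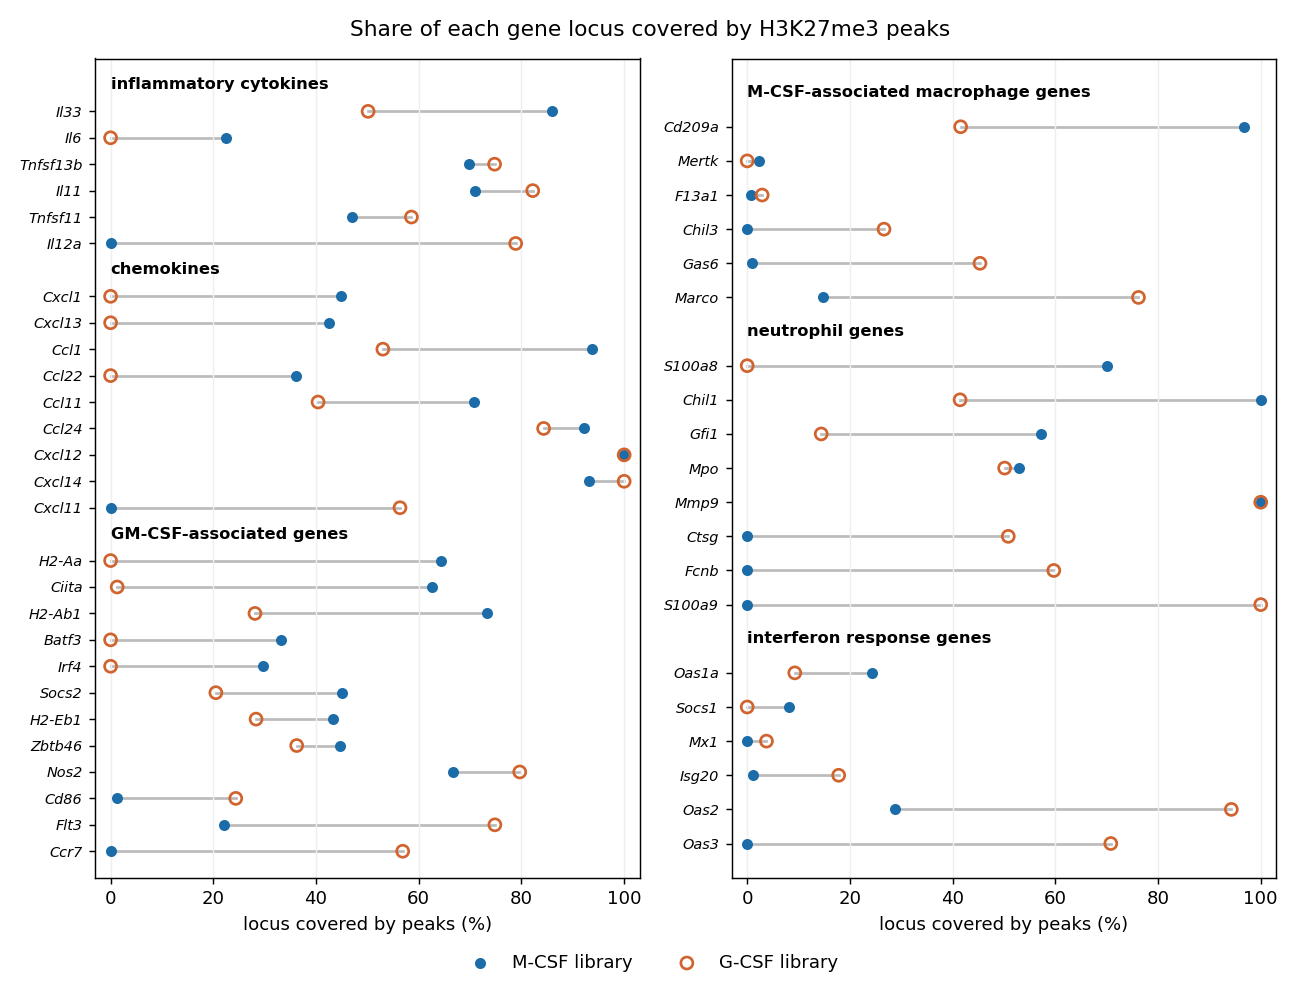
Each row gives the percent of 1 gene locus covered by peaks in the M-CSF library (filled points) and the G-CSF library (open circles), grouped by gene list and joined by a grey line. Il12a, Ccr7, Oas3 and S100a9 lie at 0% in the M-CSF library, and Il6, Cxcl1, H2-Aa and S100a8 lie at 0% in the G-CSF library.

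Neutrophil genes were examined because G-CSF is a growth factor of that lineage. Of 22 loci 6 were marked in both libraries, 1 in the M-CSF library only, 4 in the G-CSF library only and 11 in neither, a balance of -3 at percentile 7.6. The neighbouring calprotectin subunit genes were each marked in a different library, by 1 peak each that was not in the stricter 50% of its list. S100a9 was covered to 100% in the G-CSF library (chromosome 3, 90689485 to 90711780, fold enrichment 2.04) and had no M-CSF peak at its locus. Outside the locus that G-CSF peak was overlapped by a 33.1 kb M-CSF peak (90700739 to 90733823), so the peak itself was shared. S100a8 was covered to 70.1% in the M-CSF library (90667703 to 90671180, fold enrichment 2.04) and had no G-CSF peak, though G-CSF peaks covered 2.48 kb within 5 kb of it. The ficolin gene Fcnb was covered to 0% and 59.7%, the granule protease gene Ctsg to 0% and 50.8%, and the neutrophil regulator Gfi1 to 57.2% and 14.4%. The myeloperoxidase gene Mpo was covered to 52.9% and 50.1%, and the gelatinase gene Mmp9 to 100% in both. The G-CSF receptor gene Csf3r and the elastase gene Elane had no peak in either library.

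Of 29 interferon response genes 19 were bare in both libraries. The M-CSF library marked 6, against a random mean of 12 (percentile 1.06), and the G-CSF library 7, against 11.9 (percentile 3.06, inside the central 95%). These calls changed with the setting. The M-CSF count was inside with a flank of 5 kb (2.55) and peaks of at least 1 kb (4.14), and the G-CSF count outside with a flank of 1 kb (0.805), at least 500 bp covered (1.06) and no flank (0.460). The G-CSF library had peaks over the viral RNA sensors Oas3 (70.8%, with no M-CSF peak) and Oas2 (94.3%, against 28.7%), which lie side by side on chromosome 5, while Oas1a was covered to 24.2% in the M-CSF and 9.27% in the G-CSF library. The percentile of the balance of -1 was 30.1, and that of the covered difference 9.68. Both were called under some other settings. The balance lay at percentile 1.42 with a flank of 1 kb, 1.36 with at least 500 bp covered and 2.30 with 50% of the locus covered, and the covered difference at 2.04 with a flank of 1 kb and 1.97 with no flank. Over only the loci with at least 500 bp covered or with 50% of the locus covered in either library, the covered difference lay at 1.15 and 0.3. Osteoclast and matrix protease genes, relevant to joint damage, were marked in both libraries at 9 of 21 loci. The integrin gene Itgb3 was covered to 30.8% in the M-CSF and 63.8% in the G-CSF library. The aggrecanase gene Adamts4 was covered to 45.2% in the M-CSF library only, and Adamts5, another aggrecanase, to 12% in the G-CSF library only. The matrix metalloproteinase genes Mmp14 (76.9% and 54.8%) and Mmp2 (65.4% and 50.7%) were covered in both. Of 26 genes for Polycomb proteins and H3K27 demethylases 9 were marked in both. Cbx2, Cbx8 and Cbx7, subunits of Polycomb repressive complex 1, were covered to 100%, 100% and 64.5% in the M-CSF and 100%, 85.8% and 69.9% in the G-CSF library. Cbx6 was covered to 29.1% and 88.5%, Phf19 to 0% and 32.9%, and Bmi1 to 35.6% and 0%, while the methyltransferase subunit genes Ezh2, Eed and Suz12 had no peak.

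Across all genes, some loci were covered over many kilobases in 1 library with no peak of the other within 5 kb. By bases covered within 5 kb of the gene, the M-CSF list was led by Acmsd, an enzyme gene of tryptophan breakdown (42.1 kb), Cmklr1, the chemerin receptor gene (40.2 kb), and Ksr1, a Ras pathway scaffold gene (38.9 kb). The others were Tmem45a2, Zfp445, Crybg2, Rasgrp1, Ehf, Fam13b and Aldh3b3. The G-CSF list was led by Arhgap22, a Rac regulator gene (47.1 kb), Smad3, a transducer of TGF-beta signals (40.6 kb), and Csad, an enzyme gene of taurine synthesis (31.3 kb). The others were Tulp3, Stx11, Myh7b, Pmp22, Klhl12, Oas3 and Meltf. Of the 17 fixed lists, the balance lay outside the central 95% of random lists for 1 (chemokines) and the covered difference for 3 (chemokines, GM-CSF-associated genes, T and NK cell genes). That is 4 of 34 percentiles, where 5% would be 1.7.

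By the authors' annotation, 49.5% of M-CSF peaks (95% interval 49.1% to 49.9%) and 51.3% of G-CSF peaks (50.9% to 51.7%) lay in a gene element. Introns held 42.5% and 43.6%, exons 2.72% and 2.95%, 3' UTRs 2.82% and 3.17%, and 5' UTRs 1.5% and 1.63%. The authors' fold enrichments were low and alike, with a median of 2.15 in the M-CSF and 2.17 in the G-CSF list and none under 2. Most peaks did not pass a q of 0.05 by the authors' score, which may be a mean over each peak. It was met by 1299 M-CSF peaks (1.86%) and 4085 G-CSF peaks (6.87%), and the largest q was 0.470 and 0.428.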

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

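With 1 library per group no library could be left out, and no paired fit or regrouping of samples was possible; autosomes and X only changed nothing, since the lists hold no other sequence. No paired analysis was possible because each group has 1 library. Settings with no flank, 50% of the locus covered, peaks of at least 1 kb, the authors' own gene per peak and the rotated list were chosen after seeing the data. For list balances and covered differences under the other settings, 235 values kept their call, 12 fell inside and 8 went outside the central 95% of random lists, and none of the called values changed sign. These counts leave out the covered differences with at least 500 bp covered, with 50% of the locus covered and by the authors' own gene, where the covered shares are not measured anew. Another sign was taken by 15 values that lay inside the central 95% in both settings. Unless a cause is named, the cause was not tested.

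Keeping the stricter 50% of each list left 34975 and 29743 peaks by construction. The share of M-CSF peaks that were shared was then 39.5%, and it was 46.9% with lists of equal length, 38.8% with peaks within 3 kb joined, 38.8% with an overlap of 50% of the shorter peak and 52.4% for peaks of at least 1 kb. For G-CSF peaks these were 44.5%, 45.4%, 44.2%, 43.9% and 55.1%. Peaks in gene elements were 53.7% and 56.3% in the stricter 50%, and 67.0% and 68.2% of bases. Requiring 50% of the locus covered left 2834 loci in both, 579 in M-CSF only and 809 in G-CSF only, which turns the order of these classes, with 95.8% of developmental loci in each library and 0% and 2.22% of housekeeping loci. By the authors' own gene, where even a wide peak counts for at most 1 gene, developmental loci were at 47.4% and 49.5%.

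The chemokine balance was 2 in the stricter 50% and 1 with 50% of the locus covered, and the chemokine covered difference was 4.95 points in the stricter 50% and 4.02 with a flank of 5 kb. The GM-CSF-associated covered difference was 4.56 points in the stricter 50% and 4.24 with a flank of 5 kb, and these 6 values all lay inside the central 95% of random lists. The GM-CSF-associated balance was 7 with a flank of 1 kb and 6 with no flank, above the central 95%.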

Other observations

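The tests of explanations in this part, of the calling threshold, list length, growth factor and antibody label, were chosen after the results were seen, while the settings of equal length and the stricter 50% and the gene lists they use were fixed earlier.

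The X chromosome held 3.45% of the M-CSF and 3.07% of the G-CSF peaks but 1.08% and 0.997% of the covered bases, with 31.0% of its 966 loci marked in each library, against 46.7% and 45.6% of autosomal loci. Among the widest M-CSF peaks was 1 over Lifr, the LIF receptor gene (161 kb), whose locus was covered to 89.1% in the M-CSF and 91.3% in the G-CSF library. Among unshared peaks with a q of at most 0.05, the widest in the M-CSF list was 6.30 kb, in an intron of the Rac regulator gene Chn1 (chromosome 2, 73625677 to 73631981, fold enrichment 2.72). The widest in the G-CSF list, over Stx11, was 23.9 kb.

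The highest pileup of each list belonged to a short peak. A peak of 269 bp in an intron of Zc3h7a (chromosome 16, 11143982 to 11144250) had a pileup of 188.75 in the M-CSF list at a fold of 2.58. Its pileup divided by its fold was 73.1, where the median of the list was 2.12. A peak of 327 bp outside genes on chromosome 11 (109011723 to 109012049) had a pileup of 75.6, and the G-CSF list held one over the same place with 89.9.

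More than 50% of the peaks of each list had no counterpart in the other, 57.2% for M-CSF and 51.8% for G-CSF. A candidate explanation is that these peaks lie close to the calling threshold. Wide peaks could not decide it. At 10 kb or more and a q of at most 0.05 at least 99.1% were shared in each library, but 94.6% and 92.7% were shared without the q limit, and 432 of 39995 unshared M-CSF and 628 of 30831 unshared G-CSF peaks were that wide. For peaks under 1 kb with a q of at most 0.05, a peak's own closeness to the threshold was not the whole cause. They say little of the rest, since 309 of 19458 unshared M-CSF and 587 of 13468 unshared G-CSF peaks under 1 kb passed that q. At a q of at most 0.05, 36.6% of M-CSF and 37.7% of G-CSF peaks were shared, against 16.9% and 20.1% without the q limit. Their median fold was 3.04 in the M-CSF and 2.90 in the G-CSF list. Whether a counterpart lay just under the threshold of the other list cannot be seen, since the lists hold called peaks only. The growth factor of the culture stays open for both, as 1 library per group cannot separate it from differences between libraries.

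Chemokine and GM-CSF-associated loci were covered more in the M-CSF library. The M-CSF list was longer in peaks but not in covered bases. With lists of equal length the chemokine balance was 6 (percentile 99.64) and the GM-CSF-associated covered difference 6.93 points (99.65). These percentiles cannot decide on list length, since the random lists come from the same peaks and any excess over the whole list is in them too. The values themselves were little lower than the 7 loci and 7.21 points of the full lists. Peaks close to the calling threshold remain a candidate explanation that could not be separated from list size: in the stricter 50% of each list the values fell from 7 to 2 loci and from 7.21 to 4.56 points, but 40 and 60 of 100 random 50% samples of the lists were as low. Of the 8 chemokine loci marked in M-CSF only, Cxcl1 and Cxcl13 kept a peak in the stricter 50%, as did 3 of the 6 GM-CSF-associated loci and 949 of 1902 (49.9%) over all genes. The growth factor of the culture, GM-CSF in the growth protocol and G-CSF in the titles, is an open biological explanation that 1 library per group cannot test, and Flt3, Ccr7 and Cd86 went against the tilt.

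Wide peaks over developmental genes raise the question of which antibody was used. If it was against H3K4me3, as its label says, housekeeping loci would carry peaks more often than others. No more than 8.89% of them had a peak in each library taken alone, against 46.0% and 44.9% of all loci, which argues against that explanation for both lists. No biological explanation was tested for this pattern.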
